A study of Homo sapiens with 8 samples.

How the data were processed

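The series holds 8 two-colour Agilent arrays of human Flp-In-293 cells with tetracycline-inducible WT or ΔF FBXO25. Per the labels, total RNA of cells treated with tetracycline for 24 h or 48 h was amplified and labelled with Cy5 and RNA of untreated cells with Cy3, so every ratio runs from untreated to treated and no dye was swapped. The label of the untreated RNA names no time. Groups and replicate numbers (2 arrays in each of 4 groups) were taken from the sample titles. The labels call the replicates biological; p values measure the spread between these arrays only.

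The scanner files hold spot intensity values, made with Agilent Feature Extraction 10.5 per the submitters' processing notes and 9.5.3.1 per the file headers; which is right is not given in the sources used here. Arrays were scanned at 5 micron resolution per the file headers. The files also hold a log10 ratio of processed Cy5 over Cy3 signal per the file headers, which is exactly 0 on 21.8% to 35.1% of gene spots per array. The authors' value table for the series holds log2 ratios: its values lay within 0.01 of the log2 of processed Cy5 over Cy3 signal on 100% of spots of 7 arrays and on 99.87% of 1, which settles scale and direction, with column medians from -0.331 to 0.0712 that show no centring on 0. In 1 file, resaved in a spreadsheet, 67 gene names had turned into dates, so names were taken from another file. Each file has 44495 spots, of which 43118 are gene spots for 34127 probes.

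Mean signals were corrected for the median local background with normexp (offset 50) and normalized within arrays by loess, with weight 0 for control and outlier spots, in limma 3.58.1 (R 4.3.3, with the data.table package at version 1.17.8). Control spots and spots that Feature Extraction marked as non-uniform or population outliers (550 to 1255 per array) were left out, saturated spots were kept (0 in Cy3, 1 to 31 in Cy5 per array), and spots of 1 probe were averaged. Probes well above background in at least 1 channel on at least 2 arrays were kept, 20250 in all. Two-sided tests used lmFit and eBayes on 4 group means over the 8 arrays, with 4 residual and 5.08 prior degrees of freedom, and Benjamini-Hochberg adjustment over all probes tested in a comparison at a threshold of 0.05. The 8 comparisons were treated over untreated in each group, the difference between lines, the difference between times in each line, and the difference of those differences. Spike-in controls gave slopes of observed on expected ratios of 0.817 to 0.895 (correlation 0.954 to 0.997).

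Gene symbols came from accessions for 24827 probes, from current symbols for 1276 and from older symbols for 500, through a RefSeq gene table; 7524 probes kept the file's name. Coordinates are those of the files (hg18). A gene is represented by its brightest probe, and other probes that passed on the opposite side are named. The rule for named genes was fixed before the data were examined: FBXO25, and in each comparison up to 12 genes with the largest rise and up to 12 with the largest fall among those past the threshold and moving alike on every array of the group (for differences, with no overlap between the sides), or the 6 smallest p where fewer than 6 pass; and up to 4 members past the threshold per list described, or 2 where none passes.

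Also fixed beforehand were 28 gene lists. They cover ATF4 stress response, BCL2 family apoptosis, heart transcription factors and targets, cholesterol synthesis, the unfolded protein response, ERK output, fibroblast markers, mitosis, glycolysis, heat shock, hypoxia targets, immediate early genes, interferon response, kidney epithelial markers, metallothioneins, mitochondrial ribosome, neuronal and adrenal markers, NF-kB inflammation, NRF2 targets, nuclear-coded oxidative phosphorylation, p53 targets, proteasome subunits, replication histones, ribosomal proteins, S phase replication, the SCF ligase core with the F-box family, SRF cytoskeletal targets and blood cell markers. The 27 lists with at least 5 measured genes were tested over 16262 genes with camera (preset correlation 0.01), adjusted over all 216 tests. With the preset correlation 27 passed, with an estimated correlation 0 (smallest adjusted p 0.73), and with fry 31. With an estimated correlation camera works on the 4 residual degrees of freedom, so a call over 216 tests was hardly attainable. Its failure therefore does not show that correlation between genes made the calls. For heat shock in WT at 24 h the estimated correlation was -0.014, yet the unadjusted camera p went from 0.00051 to 0.021. Several other called lists had estimates well above the preset 0.01. These were 0.4 for replication histones, 0.28 for cholesterol synthesis, 0.21 for glycolysis and SRF targets and 0.16 for ATF4 targets. For cholesterol synthesis in WT at 24 h the unadjusted camera p went from 0.00033 to 0.2. In such lists correlation and the few degrees of freedom both raise the p and were not separated. Fry asks whether a list's genes move on balance 1 way and does not compare them with other genes. Where a camera or fry call is given its median, mean and test had the same sign, except for the fry call of the unfolded protein response in ΔF at 24 h (median 0.091, mean -0.026).

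Alternatives fixed beforehand were no background subtraction, a normexp offset of 1, the deposited log ratio column, the deposited value table, median centring in place of loess, scaling between arrays, no filter and a strict filter on dim probes (11571 probes above background in both channels on all arrays), robust eBayes with an intensity trend, only the arrays compared, the replicate number as a block and leaving out each array. Median centring was first run over all gene spots, as limma does by default. After its values were seen, centring over the tested probes was added, because the filter keeps brighter probes and their median had moved up in each group. Both are reported. Either centring subtracts 1 value per array, so unlike loess it leaves a trend of the ratio with intensity in place. A crossed block, leaving out probes with CCGCC, removing a GC trend and the line difference at each time were also added after seeing the data. Slide and line coincide, so neither a slide block nor a dye term could be fitted.

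The fit and its threshold were tested on simulated log2 ratios of 20250 probes, with 67, 67 and 66 probes changed by the 3 sizes. Values were drawn independently for each probe and array with the spread of the fit. Background correction, loess, averaging of spots and the filter were not run on them. For WT at 24 h, 65.7%, 98.5% and 100% of changes of 0.5, 1 and 2 on the log2 scale were recovered, with 9 false calls; for WT minus ΔF, 68.7%, 97% and 100%, with 16; for the line by time difference, 2.99%, 52.2% and 100%, with 8. In a simulation of WT at 24 h over 16262 genes and 27 lists, the 1 list shifted by 0.4 was found and 0 others were called. Its genes were drawn without correlation, so it does not show how often lists are called falsely in these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes of X inactivation and Y-linked genes were not named, and a few genes that the rule takes are not reported here. Shared untreated RNA was simulated for the overlaps between times, and the line difference was refitted over 35 splits of the 8 arrays.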

Results

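The series measured gene expression in Flp-In-293 cells, a derivative of the human embryonic kidney line HEK293 with a defined site for inserting a transgene. FBXO25, the protein under study, is an F-box protein, a class that recruits substrates to SCF ubiquitin ligases. One line carried wild-type (WT) FBXO25 under a tetracycline-inducible promoter and the other a mutant form called ΔF. What ΔF lacks is not given in the sources used here. Each of 8 two-colour arrays compared RNA of tetracycline-treated cells, labelled with Cy5, with RNA of untreated cells of the same line, labelled with Cy3. The 4 groups were WT at 24 h, WT at 48 h, ΔF at 24 h and ΔF at 48 h, with 2 arrays each, called biological replicates in the labels. Between 12564 and 18226 probes per array stood well above background in the untreated channel and between 17107 and 19726 in the treated channel. In all, 20250 of 34127 probes were tested. The number of arrays limits the precision of every value. All values are log2 ratios of treated over untreated signal with the standard error (SE) of the fit, and adjusted p values come from limma with Benjamini-Hochberg adjustment. The WT arrays lay on 1 slide and the ΔF arrays on another, so slide and line cannot be told apart. Treated RNA always carried Cy5, so a dye effect on a probe cannot be told apart from a response.

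The targeted gene was examined first. FBXO25 had 1 probe, on chromosome 8 from 408943 to 409002 (hg18), well above background in both channels on all arrays. Its log2 ratio was -0.18 (SE 0.11, adjusted p = 0.418) in WT at 24 h and -0.28 (SE 0.11, adjusted p = 0.154) in WT at 48 h. In ΔF it was -0.08 (adjusted p = 0.61) at 24 h and -0.04 (adjusted p = 0.878) at 48 h, each with an SE of 0.11. None passed the threshold, and the 95% interval in WT at 48 h ran from -0.54 to -0.03. The sign of FBXO25 depended on the normalization within arrays. With each array centred on the median of all its gene spots in place of loess, FBXO25 stood at 2.13 (adjusted p = 0.00035) in WT and 1.4 (adjusted p = 0.0045) in ΔF at 24 h and at 1.42 (adjusted p = 0.0033) and 0.74 (adjusted p = 0.099) at 48 h. That centring moved the median of all tested probes from 0.02 to 0.85 and from -0.01 to 0.45 at 24 h, and from 0.02 to 0.64 and from 0.01 to 0.31 at 48 h. Centred over the tested probes, a choice made after seeing the data, FBXO25 stood at 1.28 and 0.94 at 24 h and at 0.79 and 0.43 at 48 h. The WT minus ΔF difference did not pass with either (0.71, adjusted p = 0.083, and 0.35, adjusted p = 0.14). On WT 24 h replicate 1 the median signal above local background was 40 in Cy5 and 6.13 in Cy3. The 99th percentile of signal there was 20800 in Cy5 and 1490 in Cy3, and Cy5 was higher on every array. Centring by 1 value per array leaves such a channel difference among bright spots in the ratios. The positive values of FBXO25 are therefore no sign of induction by themselves. Whether the transgene's transcript contains the probed sequence is not given in the sources used here, so this probe checks neither the labels nor the induction.

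In WT cells at 24 h, the lists of cholesterol synthesis and of heat shock genes were shifted upward with tetracycline after loess normalization, by camera with a preset correlation. Neither call held with an estimated correlation (adjusted p = 0.73 for both), a test on 4 residual degrees of freedom that could hardly pass. Of the members, 3 of 20 and 6 of 15 rose. DHCR7, which catalyses the last step of cholesterol synthesis, rose by 0.995 (SE 0.1, adjusted p = 0.0026), with RPL38 and RPL23 of the ribosome at 1.03 and 0.88. POLR2L, a subunit of RNA polymerases, rose by 0.94, RAN, a GTPase of nuclear transport, by 0.89, HMGN2, a nucleosome-binding protein, by 0.88 and SRM, the spermidine synthase, by 0.87. C5orf63 (1.38), the histone gene H4C3 (1.27), DYTN (1.14), EVPL (0.92) and C1orf53 (0.87) completed the 12 largest rises. Without WT 24 h replicate 1, H4C3 was at 0.65, RAN at 0.47 and SRM at 1.24, and without replicate 2 at 1.89, 1.31 and 0.51. ASS1, an enzyme of arginine synthesis, fell by 1.31 (SE 0.11, adjusted p = 0.0015), the secreted protease ADAMTS1 by 1.2 and the growth factor gene IGF2 by 1.05. The DNA repair gene XRCC3 (-1.29), ADGRB2 (-1.17), TINAGL1 (-1.12), REEP2 (-1.1), METRN (-1.09), GNAZ (-1.09), SUZ12P1 (-1.07), ZDHHC11B (-1.05) and ILDR1 (-1.02) also fell. Other probes of C5orf63, RAN, XRCC3 and ADGRB2 lay between -0.01 and 0.14 and that of ASS1 at -0.38, and did not pass, while those of HMGN2, RPL23, ADAMTS1 and SUZ12P1 passed on the same side.

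The cholesterol synthesis list was shifted upward in WT at 24 h (median 0.18, 17 of 20 measured genes above 0, camera adjusted p = 0.0056 with a preset correlation, adjusted p = 0.73 with an estimated correlation). Of its genes 3 rose and 17 did not pass, or 4 passed adjusted over the list alone. Among those that rose were DHCR7 and INSIG1 (0.66). The heat shock list was also shifted upward (median 0.11, 13 of 15 genes above 0, adjusted p = 0.0069, adjusted p = 0.73 with an estimated correlation). In it 6 genes rose and 9 did not pass, or 7 adjusted over the list alone, with HSP90AA1 at 0.76, HSPE1 at 0.73, HSPH1 at 0.43 and DNAJA1 at 0.38. Without WT 24 h replicate 1 the cholesterol list had an adjusted p of 0.051 and HSPE1 was at 0.42. Without replicate 2 the heat shock list had an adjusted p of 0.084 and DNAJA1 was at 0.25. In all, 1514 of 20246 probes passed, 758 higher and 756 lower. Leaving out WT 24 h replicate 2 gave 660 probes and leaving out either WT 48 h array 880. A normexp offset of 1 gave 678, and a fit of the WT 24 h arrays alone gave 1. With median centring over all gene spots in place of loess 13722 probes passed, 92.7% of them higher against 50.1%, and all 12 genes named above as lower turned positive. Relative to the tested probes, ADGRB2 and ZDHHC11B kept their sign and the other 10 turned positive.

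In WT cells at 48 h, the lists of glycolysis, amino acid stress and SRF cytoskeletal genes were shifted upward after loess normalization, by camera with a preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.73 for each), and 4 of 20, 9 of 28 and 5 of 15 members passed the threshold upward, with 2 of the 28 lower. PKM, the pyruvate kinase of glycolysis, rose by 1.45 (SE 0.23, adjusted p = 0.0067), the cell-surface protein gene BSG by 1.52 (SE 0.18, adjusted p = 0.0033), the actin-binding profilin gene PFN1 by 1.36 and RPL23 by 1.28. DYTN (1.9), C5orf63 (1.67), TRAPPC1 (1.49), CHST6 (1.44), EVPL (1.43), SNAR-A3 (1.39), DCXR (1.34) and SH3KBP1 (1.3) were the other large rises. SEC13, a component of COPII vesicle coats, fell by 1.14 (SE 0.09, adjusted p = 0.0023), the mitochondrial protease gene CLPP by 1.07 and MCM7, a subunit of the replicative helicase, by 1.03. XRCC3 (-1.13), TINAGL1 (-1.07), ADGRB2 (-1.07), CD276 (-1.06), SYNGR2 (-1.06), NPIPB5 (-1.01), LRWD1 (-0.97), REEP2 (-0.91) and ATP6V0A1 (-0.9) also fell. Other probes of MCM7 (0.06), CD276 (0.14), XRCC3 (0.1), CHST6 (-0.1), SYNGR2 (-0.05), ADGRB2 (-0.01), SEC13 (-0.31) and C5orf63 (0.14 and 0.1) did not pass. Of SH3KBP1 1 other probe rose (0.52) and 2 did not pass (-0.06 and -0.07), and those of RPL23 (0.8) and NPIPB5 (-0.66) passed on the same side. With median centring over all gene spots in place of loess all 12 of these lower genes turned positive, and with centring over the tested probes all but ADGRB2 did.

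Among the lists in WT at 48 h, targets of ATF4, the transcription factor of amino acid stress, were shifted upward (median 0.22, 23 of 28 above 0, adjusted p = 0.014, adjusted p = 0.73 with an estimated correlation). In this list 9 genes rose, 2 fell and 17 did not pass, or 14 passed adjusted over the list alone. CHAC1 was at 1.01, WARS1 at 0.8, PSAT1 at 0.68 and SLC7A5 at 0.63. Glycolysis genes were shifted upward (median 0.22, adjusted p = 0.0067, adjusted p = 0.73 with an estimated correlation). In it 4 of 20 passed the threshold, or 9 adjusted over the list alone: PKM, PFKL (0.77), GAPDH (0.56) and ENO2 (0.35). Without WT 48 h replicate 1, PFKL was at 0.39 and the ATF4 list did not pass (adjusted p = 0.05). Cytoskeletal targets of the transcription factor SRF were shifted upward (median 0.31, adjusted p = 0.0052, adjusted p = 0.73 with an estimated correlation). Of these 5 of 15 passed the threshold, or 7 adjusted over the list alone, among them ZYX (0.83), TGFB1I1 (0.55), MYH9 (0.5) and ACTA2 (0.45). Proteasome subunits were shifted downward (median -0.09, adjusted p = 0.0036, adjusted p = 0.73 with an estimated correlation). Among subunits 6 of 30 were lower, or 7 adjusted over the list alone, led by PSMB3 (-0.76), PSMD2 (-0.71), PSMB7 (-0.56) and PSMD11 (-0.46). This proteasome shift, and each of these 4 subunits, turned upward when each array was median centred in place of loess, over all gene spots (adjusted p = 0.0019) or over the tested probes (adjusted p = 7.8e-07). In all, 2261 of 20246 probes passed, 1452 higher and 809 lower. None passed when either WT 48 h array was left out, with 2975 and 2927 probes at an unadjusted p under 0.05 in limma. Median centring over all gene spots gave 96.2% higher among 11856 probes, centring over the tested probes 50.7% higher among 14294, against 64.2% here. A normexp offset of 1 gave 920 probes and the WT 48 h arrays alone 4093.

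**Figure D1:**
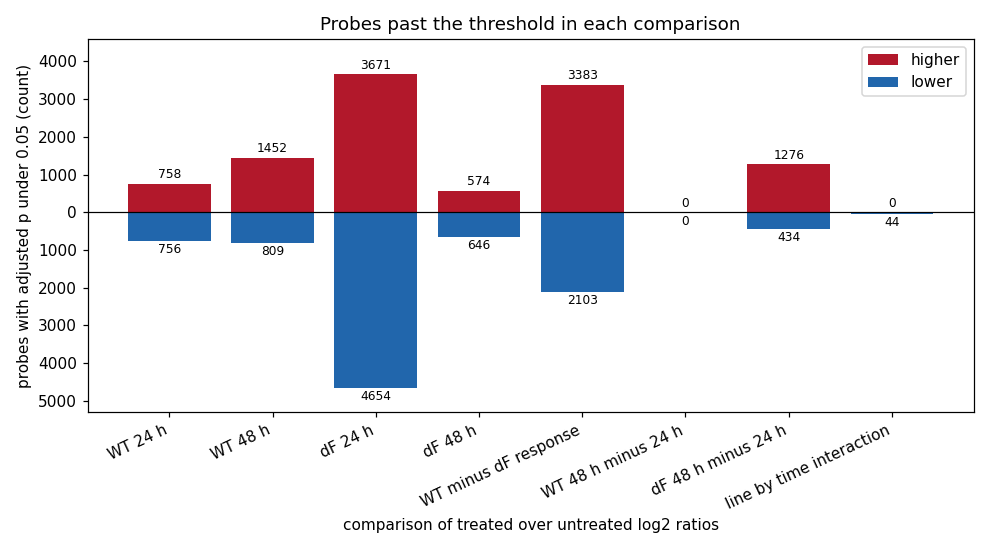
Number of probes with an adjusted p under 0.05 in each comparison (y axis, count of probes; red bars above 0, higher; blue bars below 0, lower). The ΔF 24 h arrays gave 3671 higher and 4654 lower probes, and the WT difference between times gave 0.

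The WT responses at the 2 times shared direction. Of the probes past the threshold at both times, 433 were higher in both, 463 lower in both and 0 opposite, where independent lists would share 54.3, 30.2 and 84.4. All groups share 1 estimate of each probe's spread, so their calls are not independent. Between the lines, WT at 24 h and ΔF at 48 h shared 131 higher and 171 lower, against 21.5 and 24.1. In contrast, WT at 48 h and ΔF at 24 h shared 223 higher against 263, with 649 opposite against 480. The labels of the untreated RNA name no time, so the arrays of a line may share untreated RNA. Unchanged groups simulated with untreated RNA shared within a replicate number gave a correlation of log2 changes of 0.49, against 0.713 observed. Their covariance was 0.0046, against 0.033 observed. They gave 0 shared calls, but with no probe changed hardly any call was possible, so this 0 says nothing about the overlap. Untreated RNA common to all arrays of a line and a dye effect on a probe were not simulated, so the simulation sets no limit on their part. Part of the overlap may come from shared untreated RNA. No probe passed for the difference between 48 h and 24 h in WT by limma, with 1214 at an unadjusted p under 0.05. The 6 genes with the smallest p had log2 differences of 0.65 (HTRA1), -0.57 (ATF3), -0.88 (HSP90AA1), 0.64 (TSC22D3), 0.65 (CDKN1C) and 0.76 (EVL), each with an adjusted p of 0.8. Proteasome subunits as a list lay lower at 48 h than at 24 h (median difference -0.24, 3 of 30 genes above 0, adjusted p = 1.7e-10, adjusted p = 0.73 with an estimated correlation). Their median was -0.033 and 0.216 on WT 24 h replicates 1 and 2, and -0.109 and -0.114 at 48 h. The size of the difference thus rests largely on WT 24 h replicate 2. PSMB3 was at -0.51 and PSMC1 at -0.37, neither of them past the threshold (PSMB3 turned positive with centring over the tested probes), and 8 genes past it adjusted over the list alone. Replication-dependent histones (median -0.2, adjusted p = 0.019), S phase replication genes (median -0.11, adjusted p = 0.0067) and SRF targets (median 0.16, adjusted p = 0.032) also differed, each with an adjusted p = 0.73 with an estimated correlation and 0 genes past the threshold, over all genes or adjusted over the list alone. Their members with the smallest p were H3C4 (-0.49), H1-3 (-0.48), CCNE2 (-0.43), MCM7 (-0.34), FLNA (0.51) and ACTA2 (0.3). The histone list did not pass without WT 24 h replicate 1 (adjusted p = 0.81) or WT 48 h replicate 2 (0.97), nor did the S phase list without WT 24 h replicate 2 (0.37) or WT 48 h replicate 1 (0.067). The SRF list did not pass without WT 24 h replicate 1 (0.87), WT 48 h replicate 2 (0.094) or either ΔF 48 h array (0.051). H3C4 was at -0.17 without WT 48 h replicate 2, H1-3 at -0.22 without WT 24 h replicate 1 and -0.24 without WT 48 h replicate 2, and MCM7 at -0.22 without WT 24 h replicate 2.

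The ΔF cells at 24 h had the most calls of the 4 groups after loess normalization, with 8325. With median centring over all gene spots they had 10232, fewer than WT at 24 h (13722) and 48 h (11856), and over the tested probes 12860, fewer than WT (15823 and 14294). FABP5, a fatty acid binding protein, rose by 1.21 (SE 0.09, adjusted p = 4.3e-05) and both of its other probes rose too (1.15 and 0.95). TYMS, the thymidylate synthase, rose by 1.03, the Golgi mannosidase gene MAN2A1 by 1.05, the stem cell factor gene KITLG by 1.01, BZW2 by 1.04 and TMEM167A by 1.12. CELF2 (1.16), DLEU2L (1.16), HS6ST2 (1.15) and MFSD1 (1.02) also rose. Other probes of CELF2 (-0.11), HS6ST2 (0.19) and MFSD1 (0.16) did not pass, and that of BZW2 rose (0.43). HSP90AA1 (1.17) and CTNNB1 (1.13), the gene of beta-catenin, rose by their brightest probe while another probe of each fell (-0.7 and -0.66). The largest falls were CELSR1 (-3.63, SE 0.22), NFKBIL1 (-3.59), SFTA1P (-3.5), FOXP4 (-3.41), VSX1 (-3.39), CCM2L (-3.32), ZNF467 (-3.27), MAML1 (-3.13) and LBX1 (-3.12). The small nuclear RNA RN7SK (-3.48, SE 0.39), the 28S ribosomal RNA probe RNA28SN5 (-3.26, SE 0.24) and the histone gene H3C15 (-3.31, SE 0.74) fell by similar amounts. Of these 12, 8 had a probe containing the bases CCGCC. Other probes of CELSR1 (0.3, past the threshold in the opposite direction), FOXP4 (0.06), ZNF467 (0.03) and CCM2L (-0.02) did not fall, while those of NFKBIL1 (-0.58) and MAML1 (-0.42) fell by less.

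Replication-dependent histones, which package newly made DNA, were lower in ΔF at 24 h (median -0.74, 2 of 14 above 0, adjusted p = 0.0036, adjusted p = 0.73 with an estimated correlation). In this list 8 genes fell and 6 did not pass, or 9 fell adjusted over the list alone, with H3C2 at -1.76 (SE 0.18), H3C4 at -1.7 (SE 0.13), H4C8 at -1.44 and H3C10 at -1.19. On the same 2 arrays RN7SK stood at -3.66 and -3.29, the median of the 28S ribosomal RNA probes at -3.23 and -2.8, and the median of the 5′ minus the 3′ probe of a gene at -0.23 on both. Whether the histone shifts here and below share a cause with these values was not tested. SRF cytoskeletal targets were lower too (median -0.31, adjusted p = 0.014, adjusted p = 0.73 with an estimated correlation). Of them 8 genes were down, 1 was up and 6 did not pass the threshold, or 9 past it adjusted over the list alone. The filamin gene FLNA was at -1.22, ACTG1 at -1.17, CNN2 at -0.91 and the non-muscle myosin gene MYH9 at -0.86. With median centring over all gene spots FLNA, ACTG1 and MYH9 turned positive, and over the tested probes ACTG1 did. In all, 8325 of 20242 probes passed, 3671 higher and 4654 lower, and 4694 and 4201 passed without ΔF 24 h replicate 1 and replicate 2. Median centring over all gene spots gave 95.2% higher calls and centring over the tested probes 54.2% of 12860, against 44.1% here. The 12 largest falls kept their sign under both.

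In ΔF cells at 48 h, the transcription factor gene SP1 rose by 1.27 (SE 0.26, adjusted p = 0.03), CTNNB1 by 1.23, the tight junction gene TJP1 by 1.08, HK2, the hexokinase that opens glycolysis, by 0.93 (SE 0.19, adjusted p = 0.031) and the homeobox gene HOXA13 by 0.96. TMED2 (1.06), SET (1.04), AK4 (1.02), SEC22B (1.01), SSR1 (0.99) and RPL23 (0.89) also rose, and RBBP4 rose by its brightest probe (1.11) while its other probes at -0.56 and -0.62 fell. Other probes of CTNNB1 (-0.22), SET (-0.33) and SSR1 (0.11) did not pass, while further probes of SET (0.41) and SSR1 (0.46) and that of RPL23 (0.79) rose. IGF2 fell by 1.2 (SE 0.1, adjusted p = 0.007) and the transcription factor gene CEBPD, with CCGCC in its probe, by 1.2. The other large falls were NFKBIL1 (-1.5), VSX1 (-1.5), CELSR1 (-1.49), FOXP4 (-1.47), SFTA1P (-1.41), CCM2L (-1.4), LBX1 (-1.39), ZNF467 (-1.29), UNCX (-1.29) and MAML1 (-1.27). All 12 of these lay lower still at 24 h, IGF2 at -1.64 and CEBPD at -2.47. Of the 12 largest falls, 10 had a probe containing CCGCC, and other probes of NFKBIL1, CELSR1, FOXP4, CCM2L, ZNF467 and MAML1 lay between -0.19 and 0.31 and did not pass. Without ΔF 48 h replicate 2, SP1 was at 0.54, RBBP4 at 0.35, TJP1 at 0.52, TMED2 at 0.51, SET at 0.6, AK4 at 0.47, SEC22B at 0.38, SSR1 at 0.52 and HK2 at 0.42. Without replicate 1 the lowest of these were HK2 (1.44) and SSR1 (1.46) and the highest SP1 (2.01).

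Ribosomal protein genes were shifted upward in ΔF at 48 h (median 0.2, 25 of 29 above 0, adjusted p = 0.0011, adjusted p = 0.73 with an estimated correlation), with 4 past the threshold, or 9 adjusted over the list alone, among them RPL23, RPS15 (0.6) and RPL37 (0.39). Heat shock genes were shifted upward (median 0.1, adjusted p = 0.038, adjusted p = 0.73 with an estimated correlation), with 4 of 15 past the threshold, or 5 adjusted over the list alone: HSPA1B (0.83), the collagen chaperone gene SERPINH1 (0.63), HSP90AA1 (0.54) and HSPD1 (0.32). Without ΔF 48 h replicate 1 the ribosomal list had an adjusted p of 0.1, and without replicate 2 the heat shock list had 0.15 and HSPA1B was at 0.42. Replication-dependent histones were shifted downward (median -0.39, adjusted p = 0.0011, adjusted p = 0.73 with an estimated correlation), with 4 of 14 lower, or 6 adjusted over the list alone, among them H3C4 (-0.8), H2AC6 (-0.67), H2BC5 (-0.42) and H2BC11 (-0.36), of which the last 2 turned positive with median centring over all gene spots. On these arrays RN7SK stood at -2.1 and -0.84, the 28S median at -2.13 and -0.72 and the 5′ minus 3′ median at -0.09 and -0.1. Metallothioneins, which bind zinc and copper, were shifted downward (median -0.2, adjusted p = 0.009, adjusted p = 0.73 with an estimated correlation), with MT1X (-0.47) and MT1F (-0.43) lower among 7 measured, or 3 adjusted over the list alone. MT1X turned positive with median centring over all gene spots. In all, 1220 of 20249 probes passed, 574 higher and 646 lower. This count was 0 without ΔF 48 h replicate 2, 290 without replicate 1, 456 without either WT 48 h array, 661 without either ΔF 24 h array and 1931 without either WT 24 h array. It was 0 with a normexp offset of 1 (3189 at an unadjusted p under 0.05), 6 with either deposited ratio, 375 with a robust trend fit and 459 from the ΔF 48 h arrays alone. It was 0 with median centring over all gene spots (7449 at an unadjusted p under 0.05 in limma) and 2536, 84.3% of them higher against 47%, with centring over the tested probes.

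**Figure D2:**
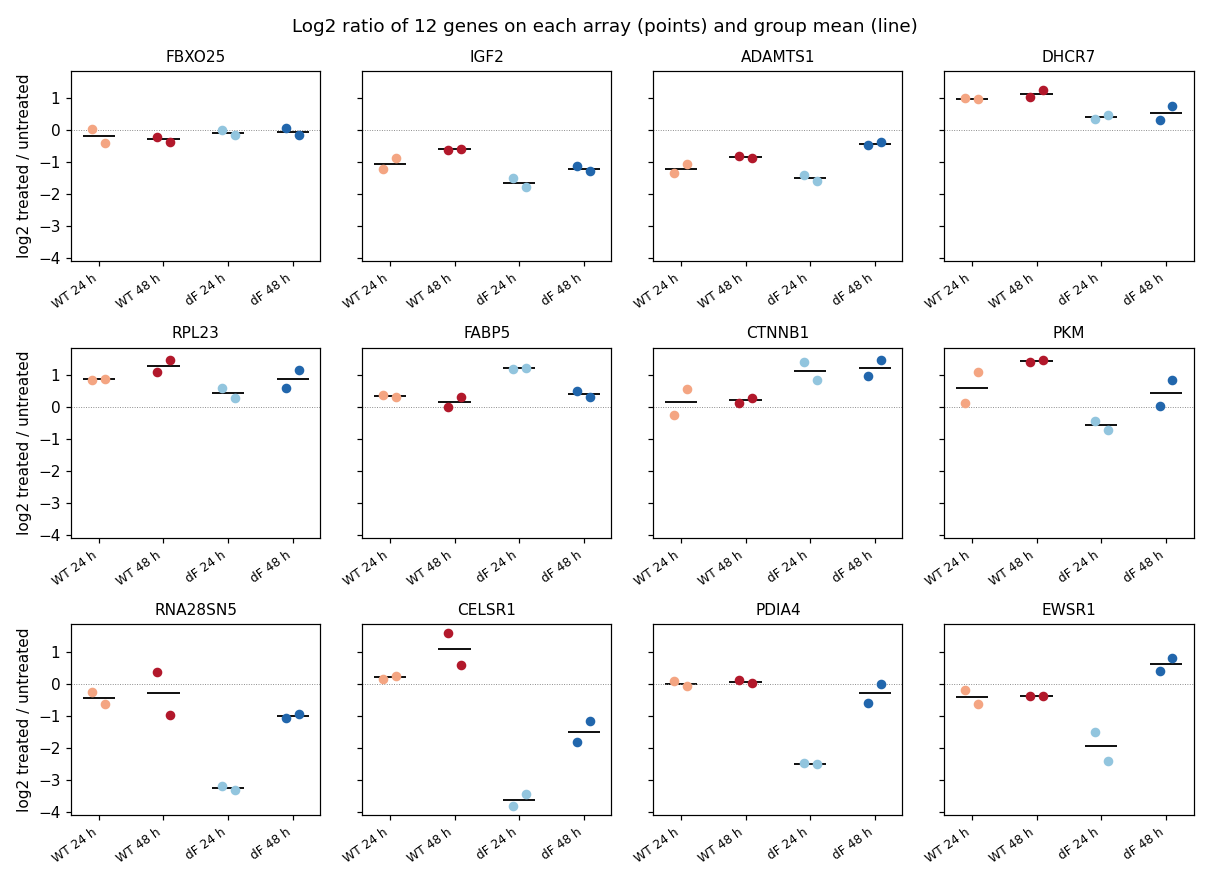
Log2 ratio of treated over untreated signal (y axis, log2) for 12 genes in the 4 groups (x axis); each point is 1 array and each line the mean of 2 arrays. After loess, FBXO25 lay near 0 in every group and IGF2 below 0 on all 8 arrays, which median centring turned above 0 for FBXO25 in every group and for IGF2 in WT at 24 h, and RNA28SN5, CELSR1 and PDIA4 were lowest on the ΔF 24 h arrays.

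The ΔF responses at the 2 times were compared next. The chaperone gene HSPA1B was higher at 48 h than at 24 h by 2.86 (SE 0.28, adjusted p = 0.0024), the splicing factor gene SRSF9 by 2.58, EWSR1 by 2.57, SNRNP40 by 2.43, RNA28SN5 by 2.27, the histone demethylase gene KDM3B by 2.24 and PDIA4, an enzyme of protein folding in the endoplasmic reticulum, by 2.2. POTEF (2.22), CORO1C (2.2), CELSR1 (2.14), NFKBIL1 (2.09) and SFTA1P (2.09) differed by similar amounts, the last 3 with CCGCC in the probe. DLEU2L (-1.07), NDUFAF4 (-0.87), OTUD6B (-0.85), UBXN8 (-0.82), TPRKB (-0.8), FABP5 (-0.8), TMEM167A (-0.79), CSTF3 (-0.77), ECHDC1 (-0.77), DOCK4 (-0.75), POLR2K (-0.74) and ID1 (-0.74) were lower at 48 h. Other probes of CELSR1 (0.01), NFKBIL1 (0.39), UBXN8 (-0.33), CSTF3 (0.26) and ECHDC1 (-0.21) did not pass, nor did 1 of EWSR1 (-0.25), while another of EWSR1 (1.63) and those of SNRNP40 (0.78) and FABP5 (-0.94 and -0.88) did. ATF4 targets were higher at 48 h (median 0.36, adjusted p = 0.0014, adjusted p = 0.73 with an estimated correlation), with 7 of 28 past the threshold, or 12 adjusted over the list alone, led by AARS1 (1.25), SLC3A2 (1.23), PHGDH (1.22) and SHMT2 (0.78). Beside this and the other list shifts between the ΔF times, RN7SK went from -3.66 and -3.29 to -2.1 and -0.84, and the 5′ minus 3′ median from -0.23 on both arrays to -0.09 and -0.1. SRF targets were higher (median 0.35, adjusted p = 0.0039, adjusted p = 0.73 with an estimated correlation), with 6 of 15 past the threshold, or 7 adjusted over the list alone, among them MYH9 (1.31), FLNA (1.18), ACTG1 (1.16) and ZYX (1.02). Glycolysis genes were higher (median 0.32, adjusted p = 0.014, adjusted p = 0.73 with an estimated correlation), with 4 up and 1 down of 20, or 9 past the threshold adjusted over the list alone: PFKL (1.56), GAPDH (0.87) and TPI1 (0.65, negative with median centring over all gene spots) were higher and the glucose transporter gene SLC2A1 (-0.67) lower. Mitotic genes were higher (median 0.36, adjusted p = 0.019, adjusted p = 0.73 with an estimated correlation), with TOP2A (0.83), TPX2 (0.81) and BUB1B (0.54) past the threshold among 25, or 12 adjusted over the list alone. Relative to all genes their median turned negative with median centring of either kind. The glycolysis list did not pass without ΔF 48 h replicate 2 (adjusted p = 0.1), nor the mitotic list without ΔF 48 h replicate 1 (adjusted p = 0.057). In all, 1710 of 20242 probes passed, 1276 higher and 434 lower. The count was 43 without ΔF 24 h replicate 2, 113 without ΔF 48 h replicate 2, 802 without ΔF 24 h replicate 1, 837 without either WT 48 h array and 2587 without either WT 24 h array. It was 0 with median centring over all gene spots (3460 at an unadjusted p under 0.05 in limma). Higher calls made up 74.6% here, 58.2% of 1911 without background subtraction, 98.8% of 81 with a normexp offset of 1, 97.1% of 104 after scaling between arrays, 90.9% of 88 in the deposited value table, 41.3% of 547 with centring over the tested probes, and 132 passed in the deposited log ratio column. Between the times, 435 probes were higher in both, 597 lower in both and 16 opposite, where independent lists would share 104, 149 and 249. Untreated RNA simulated as shared within a replicate number gave a correlation of 0.48 against 0.663 observed and a covariance of 0.0044 against 0.058. It gave 0 shared calls, which says nothing about the overlap, as no probe was changed. The limits given for the overlap in WT hold here too. Part of the overlap may come from shared untreated RNA.

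The responses of the 2 lines were compared directly. NFKBIL1 and CELSR1 were each higher in WT than in ΔF by 3.22 (adjusted p = 0.00023), followed by VSX1 (2.99), FOXP4 (2.95), RN7SK (2.95), SFTA1P (2.82), ZNF467 (2.76), UNCX (2.75), CCM2L (2.63), MAML1 (2.63), LBX1 (2.6) and BHLHE23 (2.36). Of these 12, 9 had a probe containing CCGCC and another probe of CELSR1 passed in the opposite direction (-0.27). Those of NFKBIL1 (0.37), FOXP4 (-0.02), ZNF467 (-0.04) and CCM2L (-0.04) did not pass, and that of MAML1 (0.29) passed on the same side. ZSWIM8 was lower in WT by 1.1 (SE 0.12), the histone methyltransferase gene KMT5C by 1.03 and the splicing protein gene SNRPD3 by 1.0. KAT2A, a histone acetyltransferase gene, was lower by 0.93 and H2AX, a histone variant that marks DNA breaks, by 0.84. The probe named NAA40, placed on chromosome 17 from 38741521 to 38741580 (hg18), was lower by 1.06. Whether that probe measures NAA40 was not tested. NPIPB5 (-1.02, with another probe at -0.71) and SSBP4 (-0.87) were lower too, another probe of NAA40 (0.17) did not pass, and XRCC3 (-1.03), CTNNB1 (-1), HSP90B1 (-1) and UBE2Z (-0.93) were lower by their brightest probe while another probe of each passed in the opposite direction. Replication-dependent histones were higher in WT than in ΔF (median 0.78, 9 of 14 past the threshold, over all genes or adjusted over the list alone, adjusted p = 0.0013, adjusted p = 0.73 with an estimated correlation), among them H3C2 (1.41), H3C4 (1.18), H4C8 (1.11) and H4C3 (0.94). RN7SK and the 28S probes differed between the lines too: the 28S median lay between -3.23 and -0.72 on the ΔF arrays and between -0.6 and 1.19 on the WT arrays. A common cause with the histone difference was not tested, so that difference does not show a change in DNA replication. SRF targets were also higher in WT (median 0.46, 10 of 15 past the threshold, over all genes or adjusted over the list alone, adjusted p = 0.002, adjusted p = 0.73 with an estimated correlation), among them ACTG1 (0.84), FLNA (0.83), ZYX (0.83) and TPM1 (0.52). In all, 5486 of 20237 probes passed, 3383 higher and 2103 lower in WT, and 2726 of the higher and 1526 of the lower had a call of the opposite sign in ΔF at 24 h. The count was 3228 without WT 48 h replicate 1 and, in a comparison by time chosen after seeing the data, it was 4671 from the 24 h arrays and 453 from the 48 h arrays. Median centring over all gene spots gave 93.2% higher and centring over the tested probes 49.3% of 9354, against 61.7% here. With the first, NAA40, XRCC3, NPIPB5, HSP90B1 and H2AX turned positive, and with the second NAA40 did.

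The change from 24 h to 48 h was compared between the lines. It was lower in WT than in ΔF for all 44 probes past the threshold, with the largest differences for EWSR1 (-2.54, SE 0.38), CORO1C (-2.25), SNRNP40 (-2.24), KDM3B (-2.18), the ribonucleotide reductase gene RRM2 (-2.14), the RNA helicase gene DDX3X (-2.13) and PDIA4 (-2.13, SE 0.24). BCL7A (-1.78), CCDC117 (-1.73), MAT2B (-1.69), NSRP1 (-1.67) and PRKCI (-1.61) followed. Other probes of EWSR1 (-1.87 and 0.13), SNRNP40 (-0.8), RRM2 (0.16), MAT2B (-0.48) and NSRP1 (-1.05) did not pass. Histones (median -0.48, adjusted p = 0.0011), ATF4 targets (median -0.28, adjusted p = 0.0056), SRF targets (median -0.3, adjusted p = 0.034) and mitotic genes (median -0.26, adjusted p = 0.019) were shifted downward and metallothioneins upward (median 0.23, adjusted p = 0.036), each with an adjusted p = 0.73 with an estimated correlation. Between the same ΔF times the 28S median went from -3.23 and -2.8 to -2.13 and -0.72, with RN7SK and the 5′ minus 3′ median moving as given above. None of these lists' members passed over all genes, and adjusted over the list alone 4 histones, 1 ATF4 target, 1 SRF target, 0 mitotic genes and 0 metallothioneins did. H3C4 stood at -1.39, H3C2 at -1.67, AARS1 at -0.99, PHGDH at -0.86 (positive with median centring of either kind), MYH9 at -0.94, TPM1 at -0.58, TOP2A at -0.68, NEK2 at -0.56, MT1E at 0.47 and MT1H at 0.28. The histone list did not pass without WT 24 h replicate 1 (adjusted p = 0.052), nor the ATF4 list without ΔF 24 h replicate 2 (0.089). The mitotic list did not pass without WT 24 h replicate 2 (0.37), WT 48 h replicate 1 (0.18), ΔF 24 h replicate 2 (0.065) or ΔF 48 h replicate 1 (0.057). Metallothioneins did not pass without WT 24 h replicate 1 (0.14), WT 48 h replicate 1 (0.071), ΔF 24 h replicate 2 (0.17) or either ΔF 48 h array (0.051 and 0.081). SRF targets did not pass without WT 24 h replicate 2 (0.3), WT 48 h replicate 1 (0.059), ΔF 24 h replicate 2 (0.11) or either ΔF 48 h array (0.051 and 0.1). The count of 44 was 0 without WT 48 h replicate 2, ΔF 24 h replicate 2 or ΔF 48 h replicate 2, 1 without WT 48 h replicate 1, 14, 18 and 27 without ΔF 24 h replicate 1, ΔF 48 h replicate 1 and WT 24 h replicate 2, and 287 without WT 24 h replicate 1. It was 0 with a normexp offset of 1, median centring over all gene spots, scaling between arrays or either deposited ratio, and 1 without background subtraction.

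The lists closest to FBXO25 itself did not pass in camera with a preset correlation in any comparison. Fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes, called some of them. Core SCF subunits and F-box genes had a smallest camera adjusted p of 0.27, in ΔF at 48 h, where FBXO38 (0.48) rose and FBXO2 (-0.47) and FBH1 (-0.37) fell among 24. In WT, FBXO7 rose at 24 h (0.46) and at 48 h (0.56), and NEDD8, whose product activates cullins, rose at 48 h (0.41). Fry called this list upward in WT at 24 h (adjusted p = 0.035) and in ΔF at 24 h (0.034) and 48 h (0.027), with medians of 0.057, 0.0027 and 0.062. In ΔF at 24 h 7 of its 24 genes rose and 6 fell, with 12 above 0. Beside these and the other list calls in ΔF, RN7SK, the 28S probes and the 5′ minus 3′ median were below 0 on all 4 ΔF arrays, at the values given for each time above. Heart transcription factors and their targets had a smallest camera adjusted p of 0.32 among 10 measured genes. Fry called them upward in WT at 24 h (adjusted p = 0.036) and 48 h (0.023), for WT minus ΔF (0.0094) and for ΔF 48 h minus 24 h (0.011), and downward in ΔF at 24 h (0.0094) and for the line by time difference (0.034). In this list GATA6 (0.47) rose in WT at 24 h and GATA4 (0.43) at 48 h, while in ΔF at 24 h 2 of the 10 rose and 3 fell. There NKX2-5 (-2.79, with CCGCC in its probe), GATA6 (-0.89) and TNNI3 (-0.59) fell and MEF2C (0.38) rose. Genes of ERK signalling output had a smallest camera adjusted p of 0.38 and a fry adjusted p of 0.036, upward, in ΔF at 24 h, where 6 rose and 3 fell of 18, with MYC (-0.69) lower and the ERK phosphatase gene DUSP6 (0.51) higher in WT at 24 h. Apoptosis genes of the BCL2 family had a smallest camera adjusted p of 0.097, in WT at 24 h, where fry called them downward (adjusted p = 0.036). The death effector genes BBC3 (-0.79) and BAX (-0.56, or -0.35 without WT 24 h replicate 2) fell there; HAX1 (0.48) rose in WT at 48 h. MYC, BBC3 and BAX turned positive with median centring of either kind, and GATA6 in ΔF with that over all gene spots.

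**Figure D3:**
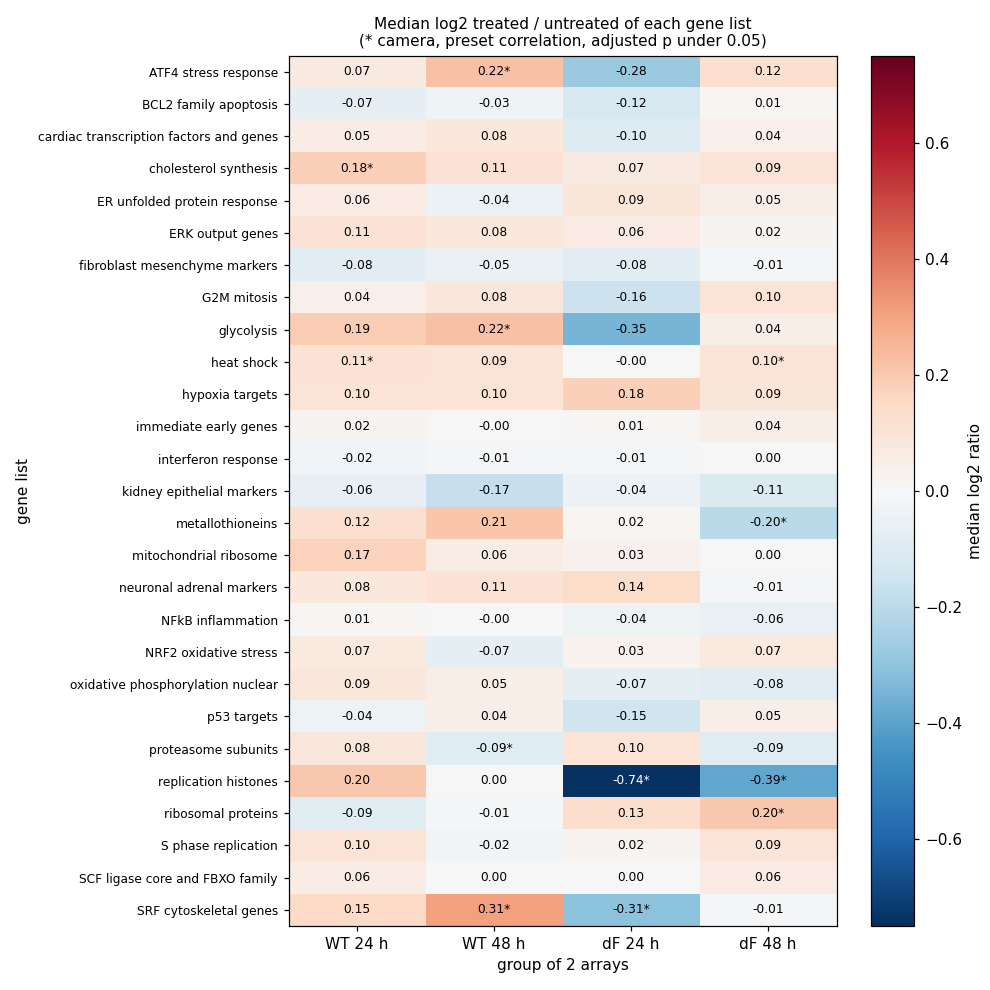
Median log2 ratio of treated over untreated signal for each of 27 gene lists (y axis) in the 4 groups (x axis), from blue (negative) to red (positive); an asterisk marks a camera adjusted p under 0.05 with a preset correlation. Replication histones were at -0.74 and -0.39 in ΔF; no asterisk remained with an estimated correlation, and the proteasome value of -0.09 in WT at 48 h turned above all genes with median centring in place of loess.

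Lists for other processes did not pass in camera with a preset correlation in any of the 8 comparisons. The smallest camera adjusted p was 0.075 for the unfolded protein response, 0.061 for nuclear-coded oxidative phosphorylation, 0.11 for hypoxia targets, 0.11 for the mitochondrial ribosome, 0.16 for NRF2 targets, 0.21 for interferon response, 0.27 for NF-kB inflammation, 0.4 for p53 targets and 0.8 for immediate early genes. Fry called hypoxia targets upward in WT at 24 h (adjusted p = 0.034), where 0 of 17 passed, and at 48 h (0.027), where 4 rose. In ΔF fry called them upward at 24 h, where 6 rose and 4 fell, and at 48 h, where 3 rose (0.018 each). It called nuclear-coded oxidative phosphorylation downward in ΔF at 24 h (0.034) and 48 h (0.046) and higher for WT minus ΔF (0.018). Of its 30 genes 4 rose and 9 fell in ΔF at 24 h, 1 fell at 48 h and 7 were higher for WT minus ΔF. Fry called the unfolded protein response upward in ΔF at 24 h (0.044), where 7 genes rose and 4 fell, and its median (0.091) and mean (-0.026) differed in sign. On the ΔF arrays of these calls RN7SK stood at -3.66 and -3.29 at 24 h and at -2.1 and -0.84 at 48 h. The 28S median stood at -3.23 and -2.8, then -2.13 and -0.72, and the 5′ minus 3′ median at -0.23 on both, then -0.09 and -0.1. Single members still changed: the interferon-induced gene BST2 fell in WT at 24 h (-0.76), in WT at 48 h (-0.45), in ΔF at 24 h (-0.89) and in ΔF at 48 h (-0.77), and turned positive in all of these but the last with median centring over all gene spots. Among markers of cell types, the kidney epithelial list had a smallest camera adjusted p of 0.051, and fry called it downward in WT at 24 h (adjusted p = 0.036) and 48 h (0.034), with KRT19 lower in all 4 groups (-0.58, -0.65, -0.65 and -0.29) and positive in all 4 with median centring of either kind. The neuronal and adrenal list had a smallest camera adjusted p of 0.097, with INA (0.5) and CHGA (0.46, or 0.31 without replicate 1) higher in WT at 24 h. The fibroblast list had a smallest camera adjusted p of 0.42, and blood cell markers had 4 measured genes and were not tested.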

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

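The tests of probe sequence, ribosomal RNA, GC content, RNA degradation and a larger response at 24 h were chosen only after the result was seen, and those of dye bias and of other splits of the arrays before. The results below were singled out because a test of the difference between lines, between times or between both passed its threshold.

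For WT minus ΔF, 5486 probes passed. Higher in WT were NFKBIL1 (3.22), CELSR1 (3.22), VSX1 (2.99), FOXP4 (2.95), RN7SK (2.95), SFTA1P (2.82), ZNF467 (2.76), UNCX (2.75), CCM2L (2.63), MAML1 (2.63), LBX1 (2.6) and BHLHE23 (2.36), and lower were ZSWIM8 (-1.1), NAA40 (-1.06), XRCC3 (-1.03), KMT5C (-1.03), NPIPB5 (-1.02), SNRPD3 (-1), CTNNB1 (-0.997), HSP90B1 (-0.996), KAT2A (-0.933), UBE2Z (-0.928), SSBP4 (-0.874) and H2AX (-0.844). The median difference was 0.78 for replication histones and 0.46 for SRF targets. In a fit of 2 groups, the real split of the 8 arrays gave 3090 probes and the highest of the other splits 0, so 1 of 35 splits gave as many. Each line lay on its own slide, so the real split is also the split by slide and every other split mixes the slides. Replicates correlated at 0.42 to 0.91, so the arrays are not interchangeable and the splits do not decide whether chance is excluded.

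For ΔF 48 h minus 24 h, 1710 probes passed. The largest values were HSPA1B (2.86), SRSF9 (2.58), EWSR1 (2.57), SNRNP40 (2.43), RNA28SN5 (2.27), KDM3B (2.24), POTEF (2.22), CORO1C (2.2), PDIA4 (2.2), CELSR1 (2.14), NFKBIL1 (2.09) and SFTA1P (2.09), and the lowest DLEU2L (-1.07), NDUFAF4 (-0.865), OTUD6B (-0.848), UBXN8 (-0.822), TPRKB (-0.802), FABP5 (-0.799), TMEM167A (-0.788), CSTF3 (-0.771), ECHDC1 (-0.768), DOCK4 (-0.745), POLR2K (-0.744) and ID1 (-0.741). List medians were 0.36 for ATF4 targets, 0.36 for mitotic genes, 0.32 for glycolysis and 0.35 for SRF targets. For WT 48 h minus 24 h, list medians were -0.24 for proteasome subunits, -0.2 for replication histones, -0.11 for S phase genes and 0.16 for SRF targets.

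For the line by time difference, 44 probes passed, with EWSR1 (-2.54), CORO1C (-2.25), SNRNP40 (-2.24), KDM3B (-2.18), RRM2 (-2.14), DDX3X (-2.13), PDIA4 (-2.13), BCL7A (-1.78), CCDC117 (-1.73), MAT2B (-1.69), NSRP1 (-1.67) and PRKCI (-1.61) the lowest. List medians were -0.28 for ATF4 targets, -0.26 for mitotic genes, 0.23 for metallothioneins, -0.48 for replication histones and -0.3 for SRF targets. None of the list calls in these differences held with an estimated correlation.

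The bases CCGCC, a motif picked on these arrays, were enriched among the probes that fell most on the ΔF 24 h arrays. Of 204 probes below -1.5, 64 (31.4%) contained them, against 329 of 20046 other probes (1.64%), and the remaining probes below -1.5 lack them and are not covered by what follows. Other probes of the same genes, without the motif, had a median of -0.0913 (27 probes for 64 genes, quartiles -0.498 to 0.0482). For genes with such a probe, this argues against a fall of their transcripts as a whole and goes with labelled RNA binding the motif. Genes without another probe are not covered. The 28S ribosomal RNA probes fell too (median -3.02), and on the mean of the WT 48 h arrays their median minus that of the fallen CCGCC probes was -0.236, with the 4 probes spread from -0.286 to 0.995. That closeness rests on replicate 1 (1.19 for 28S, 1.14 for CCGCC), since on replicate 2 the medians lay on opposite sides (-0.16 and 0.37), and on WT 24 h replicate 2 they were -0.6 and -0.11. Whether carried-over ribosomal RNA is the bound RNA therefore stays open. A change in the level of ribosomal or other GC-rich RNA in treated ΔF cells stays open, as untested.

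The ΔF 24 h arrays gave 8325 probes against 1220 at 48 h. With the GC trend removed from each array the ratio of the counts was 7.32, which argues against GC content as the whole cause, although the log2 ratios correlated with probe GC percent at -0.41 and -0.39 (Spearman, across probes) on the ΔF 24 h arrays. Within 2178 genes with a call, the 5′ probe lay below the 3′ probe by a median difference of -0.24. Its 95% interval, -0.266 to -0.219, came from resampling genes and does not measure the spread between arrays. Degraded treated RNA was taken to need below -0.5 and its absence above -0.1. Degradation of the treated RNA could therefore not be excluded, and it cannot be told apart from a larger response of this line at 24 h, since each group lay on 2 arrays of 1 slide.

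Probes on the same side on all 8 arrays numbered 2590 (1392 higher, 1198 lower). Independent arrays would give 0.781% of the probes by chance, but arrays of a line correlated at 0.42 to 0.91, so that share does not apply. Among 565 such genes with another probe, 69.7% (95% interval 65.8% to 73.5%) had it on the same side, between the 60% set for dye bias of single probes and the 80% set against it, and 85.9% of 64 genes beyond 0.5 did. Dye bias and a response to tetracycline or to either construct cannot be told apart, since no dye was swapped and every treated sample carried Cy5. The side of a probe here is that after loess, and most of the lower genes with the largest means turned positive with median centring over all gene spots.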

How the results depend on the processing

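Median centring over the tested probes, the crossed replicate block, the fits without CCGCC probes or with the GC trend removed, and the line difference at each time were chosen after seeing the data; the other alternatives were fixed before. Centring over the tested probes came after centring over all gene spots, fixed before, had moved the tested probes' median and turned many named genes. Probes moved by unequal amounts over all gene spots. The mean of RPL23 over the 8 arrays went from 0.871 to 3.18 and that of RASGRP2 from -0.936 to -0.236. Either centring subtracts 1 value per array, so unlike loess it leaves a trend of the ratio with intensity in place. For each change below the cause was not tested, apart from fits with fewer arrays, which have fewer residual degrees of freedom. The count of 5486 probes for WT minus ΔF stayed within 1.5 times under every alternative fixed before that keeps all arrays. The probes called were partly different ones. Of the 5486, between 3169 (median centring over all gene spots) and 5282 (no filter) kept their call under these alternatives. A normexp offset of 1 kept 3352, and the deposited ratios kept 3398 (log ratio column) and 3305 (series values). In WT at 24 h, 616 of the 1514 kept their call with the deposited log ratio column, which gave 1247. The 0 of WT 48 h minus 24 h stayed at 0 under each alternative fixed before. That 0 came from limma, with 1214 probes at an unadjusted p under 0.05.

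A normexp offset of 1 gave 678 probes in WT at 24 h, 920 in WT at 48 h, 0 in ΔF at 48 h, 81 for ΔF 48 h minus 24 h and 0 for the line by time difference. The deposited log ratio column gave 6, 132 and 0 for the last 3 and the deposited values of the series gave 6, 88 and 0. Without background subtraction the line by time difference had 1 probe. Scaling between arrays gave 104 for ΔF 48 h minus 24 h and 0 for the line by time difference, and robust eBayes with an intensity trend gave 375 in ΔF at 48 h and 20 for the line by time difference. Fits of only the arrays compared gave 1 in WT at 24 h, 4093 in WT at 48 h and 459 in ΔF at 48 h, and the line difference at 48 h alone 453. Median centring over all gene spots gave 13722 and 11856 probes in WT at 24 h and 48 h, and 0 in ΔF at 48 h, for ΔF 48 h minus 24 h and for the line by time difference. Centring over the tested probes gave 15823, 14294, 12860 and 2536 in the 4 groups in the order WT 24 h, WT 48 h, ΔF 24 h and ΔF 48 h, 9354 for WT minus ΔF, 1 for WT 48 h minus 24 h, 547 for ΔF 48 h minus 24 h and 6 for the line by time difference.

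Of 27 list shifts past the threshold, 0 remained in camera with an estimated correlation (10 of 216 at an unadjusted p under 0.05). That test has 4 residual degrees of freedom and could hardly pass over 216 tests, so it does not decide whether the shifts hold. The count was 60 with median centring over all gene spots and 78 over the tested probes. Of the same 27, these kept 12 and 17. It was 12 with the deposited log ratio column and 31 with fry, which kept 12 and 7 of the 27. The proteasome shift in WT at 48 h reversed in camera with an adjusted p of 0.0019 and 7.8e-07 under the 2 kinds of median centring.

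Leaving out each array in turn gave 660 to 1428 probes in WT at 24 h, 0 to 2856 in WT at 48 h, 4201 to 8919 in ΔF at 24 h, 0 to 1931 in ΔF at 48 h, 3228 to 5557 for WT minus ΔF, 0 to 0 for WT 48 h minus 24 h, 43 to 2587 for ΔF 48 h minus 24 h, 0 to 287 for the line by time difference and 22 to 33 list shifts. The lowest counts came without WT 24 h replicate 2 (660), either WT 48 h array (0), ΔF 24 h replicate 2 (4201 and 43) and ΔF 48 h replicate 2 (0), and for WT minus ΔF without WT 48 h replicate 1 (3228). Of the 246 named calls, 151 were lost without at least 1 array, 18 moved by over 1.5 times and 0 reversed. A group left with 1 array is assumed to vary like the others. FBXO25 ranged from -0.403 to 0.0488 in WT at 24 h, from -0.16 to 0.0811 in ΔF at 48 h, from -0.332 to 0.12 for WT 48 h minus 24 h, from -0.0806 to 0.161 for ΔF 48 h minus 24 h and from -0.372 to 0.0798 for the line by time difference.

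Of 270 named results other than FBXO25, 246 of them past the threshold, 118 kept their direction and side of it with median centring over all gene spots, 100 lost the call and 52 reversed; over the tested probes 194, 40 and 36. None of these 270 reversed under another setting that keeps all arrays, and between 159 (the deposited value table) and 266 (no filter) kept direction and side under the other settings fixed before and run on all of them. The log2 values that reversed over all gene spots, FBXO25 included, were as follows. In WT at 24 h FBXO25 2.13, ASS1 0.863, XRCC3 1.67, ADAMTS1 0.872, ADGRB2 0.765, TINAGL1 1.38, REEP2 1.68, METRN 1.58, GNAZ 1.06, SUZ12P1 2.1, IGF2 0.918, ZDHHC11B 0.789, ILDR1 1.44, BBC3 1.35, BAX 1.46, MYC 1.43, BST2 0.601, KRT19 2.35. In WT at 48 h FBXO25 1.42, SEC13 1.12, XRCC3 1.22, TINAGL1 0.801, ADGRB2 0.353, CLPP 1.07, CD276 0.96, SYNGR2 1.23, MCM7 1.55, NPIPB5 1.34, LRWD1 0.718, REEP2 1.23, ATP6V0A1 0.99, KRT19 1.54, PSMB3 1.24, PSMD2 1.54, PSMB7 1.55, PSMD11 1, BST2 0.623. In ΔF at 24 h FBXO25 1.4, GATA6 0.154, KRT19 1.1, FLNA 0.119, ACTG1 0.565, MYH9 0.194, BST2 0.18. In ΔF at 48 h FBXO25 0.74, MT1X 0.133, H2BC11 0.0981, H2BC5 0.226, KRT19 0.654. For WT minus ΔF FBXO25 0.707, NAA40 0.364, XRCC3 0.121, NPIPB5 0.142, HSP90B1 0.205, H2AX 0.162. For ΔF 48 h minus 24 h FBXO25 -0.658, TPI1 -0.124. For the line by time difference PHGDH 0.509.

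The log2 values that reversed over the tested probes, FBXO25 included, were as follows. In WT at 24 h FBXO25 1.28, ASS1 0.0122, XRCC3 0.817, ADAMTS1 0.0216, TINAGL1 0.529, REEP2 0.831, METRN 0.728, GNAZ 0.207, SUZ12P1 1.25, IGF2 0.0673, ILDR1 0.594, BBC3 0.495, BAX 0.611, MYC 0.582, KRT19 1.5. In WT at 48 h FBXO25 0.787, SEC13 0.481, XRCC3 0.58, TINAGL1 0.166, CLPP 0.43, CD276 0.325, SYNGR2 0.591, MCM7 0.912, NPIPB5 0.705, LRWD1 0.0827, REEP2 0.592, ATP6V0A1 0.355, KRT19 0.907, PSMB3 0.603, PSMD2 0.906, PSMB7 0.911, PSMD11 0.365. In ΔF at 24 h FBXO25 0.941, KRT19 0.639, ACTG1 0.108. In ΔF at 48 h FBXO25 0.433, KRT19 0.348. For WT minus ΔF FBXO25 0.346, NAA40 0.0027. For ΔF 48 h minus 24 h FBXO25 -0.508. For the line by time difference FBXO25 0.0159, PHGDH 0.574. For WT 48 h minus 24 h PSMB3 0.152. For ΔF 48 h minus 24 h, FBXO25 was also -0.00237 without background subtraction and -0.0383 with the deposited log ratio column or value table.

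With the replicate number as a block, the counts were 1416, 2113, 8267 and 1070 in the 4 groups in the order above, 5398 for WT minus ΔF, 0 for WT 48 h minus 24 h, 1337 for ΔF 48 h minus 24 h, 32 for the line by time difference and 28 list shifts. Differences between replicates correlated at 0.45 between the WT times and 0.32 between the ΔF times but at -0.35 to -0.14 between the lines, so the numbers pair the arrays of a line at best, not all samples. With the ΔF numbers exchanged the counts were 2123, 3054, 8993 and 2116 in the 4 groups, 6275, 0, 2756 and 146 for the differences and 29 list shifts. Of the 270 named results, 18 lost the call with the replicate block and 4 gained one with the ΔF numbers exchanged. Dim probes limit the ratios: in the untreated channel the median signal above local background was 6 to 6.94 on the WT arrays and 14.1 to 16.2 on the ΔF arrays, and the ratios used here had slopes on the deposited ratios of 0.588 to 0.62 (WT) and 0.703 to 0.736 (ΔF).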

Other observations

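Several genes lay on the same side in both lines and at both times, on all 8 arrays after loess normalization, and were picked for that after their values were seen. Median centring raised the means of the genes named here. The higher ones therefore kept their side, and over all gene spots most of the lower ones did not. The growth factor gene IGF2 had a mean log2 ratio of -1.12 over the 8 arrays (SD 0.42, from -1.8 to -0.59), and the apolipoprotein gene APOE -0.999 (SD 0.21) and the protease gene ADAMTS1 -0.989 (SD 0.43). Also low were RASGRP2 (-0.936), METRN (-0.861), the serine protease gene PRSS8 (-0.813) and GNAZ (-0.76). On the high side stood C5orf63 (1.03), RPL23 (0.871), the histone chaperone gene SET (0.815), DHCR7 (0.775), BANF1 (0.752), TYMS (0.711), HMGN2 (0.691) and the ketone body enzyme gene OXCT1 (0.649). Each of these 8 higher genes stayed above 0 on all 8 arrays with median centring of either kind. As that centring moved C5orf63 to 3.28 and HMGN2 to 3.01 over all gene spots, it could hardly turn a higher gene and is no check of them. With median centring over all gene spots the mean turned positive for IGF2 (0.226), APOE (0.74), ADAMTS1 (0.422), METRN (0.949) and GNAZ (0.744). RASGRP2 (-0.236, below 0 on 6 arrays) and PRSS8 (-0.134, below 0 on 7) stayed negative. Over the tested probes, a choice made after seeing the data, APOE (0.177), METRN (0.386) and GNAZ (0.182) were positive. IGF2 (-0.336) and ADAMTS1 (-0.14) stayed negative with 5 arrays below 0 each, and RASGRP2 (-0.798) and PRSS8 (-0.697) with all 8. The values describe these arrays only. A comparison of cells without either transgene, with and without tetracycline, was not analysed here.

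The treated ΔF RNA at 24 h differed from the others in several measured ways at once. The small nuclear RNA RN7SK stood at -3.66 and -3.29 on these arrays, at -2.1 and -0.84 on the ΔF 48 h arrays and between -0.58 and 1.42 on the WT arrays. The median of the 28S ribosomal RNA probes was -3.23 and -2.8, then -2.13 and -0.72 at 48 h, and ran from -0.6 to 1.19 in WT. Replicates correlated at 0.91 across probes in ΔF at 24 h, 0.56 in ΔF at 48 h, 0.79 in WT at 48 h and 0.42 in WT at 24 h; probes are not independent replicates.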
